A study of Homo sapiens with 6 samples.

How the data were processed

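The series holds 6 libraries from HL-60, a human promyelocytic leukaemia cell line whose labels give the cell type as myeloblast. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done for H3K4me3 and for H3K27me3, in parental cells and in cells knocked out for JMJD3, with 1 library per genotype and mark. A matching input library of each genotype, 2 in all, was not analysed here. Per the labels' protocols, nuclei were sonicated, histone-DNA complexes were isolated with an antibody, and the libraries were amplified, selected by size on a gel and sequenced on an Illumina Genome Analyzer. The submitters' processing notes name BWA 0.7.10, SAMtools, MACS2 2.1.1 and the genome build hg19; which setting each tool was run with, and whether the inputs served as controls for peak calling, is not given in the sources used here. The titles of the H3K27me3 libraries name H3K27me3, while their antibody label names H3K4me3 with a catalogue number, so the mark was taken from the title.

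Each of the 4 deposited files is a peak list joined to RefSeq transcripts, with 1 line for each pair of a peak and a transcript start site (TSS). Per the file headers, a line holds the chromosome, the peak's start and end, a peak name, the transcript, the gene symbol, a distance and a score. The distance was tested on the values and is the peak centre minus the TSS in the direction of the genome, and in all 4 files it stays under 20 kb in size. The score deposited by the authors is a function of the distance alone: exp of minus the sum of 0.5 and 4 times the distance divided by the 20 kb limit reproduced it with an error of at most 5e-13. The score was therefore not used as a measure of peak strength. The lists hold neither read counts nor peak heights, so sequencing depth is unknown and a longer or wider list can reflect a deeper or cleaner library. Peak names carry numbers that run beyond the number of peaks listed; where the numbered peaks with no line lie is not given in the sources used here, and they were not analysed here. Coordinates are printed as hg19 positions counted from 1, on the reading that starts are counted from 0 as in BED files, which the sources used here do not state; a different convention would move starts by 1 bp.

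Distinct peaks were counted by chromosome, start and end. Peak sets were compared with bedtools 2.31.1, and a peak was shared when at least 1 bp was overlapped. Intervals of shares are Wilson 95% binomial intervals, and intervals of peak ratios come from the Wilson interval of the knockout share of both lists; neighbouring peaks are not independent, so these intervals cover counting error only. A gene was marked at its promoter when a peak centre was listed at most 5 kb from the TSS of any of its transcripts, or when a peak spanned the TSS. The summed width of a gene's distinct promoter peaks was compared between genotypes as a log2 ratio for genes marked in both lists. Width is a measure of the extent of the called region and not of the amount of the mark. Expected numbers of shared genes were computed as the product of both list sizes divided by the 18086 gene symbols that appear in any of the 4 files. Genes with no line in any file are left out, which raises these expected numbers. Of these symbols 16271 matched a RefSeq symbol of GRCh38.p14 and 1225 more matched an older name there; that table was used for names only.

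With 1 library per genotype and mark, no test across replicates exists, and no p-value is given. For 17 gene lists fixed before the data were examined, the net share of members marked in the knockout list only minus those in the parental list only was placed among 10000 random lists of the same size. The random lists were matched in 5 classes of the mean summed promoter width of both libraries, and a list stood apart when its percentile was at most 2.5 or at least 97.5. A gene unmarked in 1 library has a lower mean width for that reason, so this matching takes up a part of the change. The median log2 width ratio of list members marked in both genotypes was placed in the same way; this second measure was added after the values were seen. Percentiles describe these libraries and not the genotypes. On simulated data with 18000 genes and lists of 25 members, 17 of 400 unchanged lists stood apart, and lists with 25% of their members lost were found in 98 of 100 cases. The lists with planted losses held only genes marked in the simulated parental list, whereas many members of the fixed lists were unmarked. How often such a loss would be found in the fixed lists is therefore not known.

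Genes are named by a rule fixed before the data were examined: JMJD3 itself (gene KDM6B), 7 fixed genes, up to 4 members of each list whose state differed, the 8 widest genes of each state per mark, and the 4 widest gains and losses among genes marked in both lists. A gene that the rule names is not reported here. Genes or regions outside this rule are said to have been chosen after their values were seen. Alternatives fixed beforehand were the widest peaks of each list, lists of equal length, stricter overlap, merging of peaks within 2 kb, chromosomes 1 to 22 only, promoter windows of 1 kb and 10 kb, peaks that span the TSS, the nearest gene only and unmatched random lists. Alternatives added later were peaks of at least 300 bp, gene counts without the regions where H3K4me3 peak counts fell most, and random lists matched on parental width. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.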

Results

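HL-60 is a leukaemia cell line of the granulocyte lineage. JMJD3, encoded by KDM6B, is a demethylase that removes methyl groups from lysine 27 of histone H3. H3K27me3 marks chromatin repressed by Polycomb complexes, and H3K4me3 marks active or poised promoters. The comparison asks where each mark lay in parental cells and in JMJD3 knockout cells. Of 6 libraries, the 4 immunoprecipitated ones were compared, 1 per genotype and mark, so no difference below has a replicate check and the sequencing depth is unknown. The H3K4me3 lists held 33470 peaks in parental and 24943 in knockout cells, covering 17.5 and 8.29 Mb. The H3K27me3 lists held 3578 and 3234 peaks, covering 4.22 and 4.17 Mb. H3K4me3 peaks gathered at start sites in both genotypes: 58.7% of parental and 62.3% of knockout peaks had a TSS within 1 kb. H3K27me3 peaks did not, with 6.43% and 5.69% within 1 kb. Of the pairs of an H3K27me3 peak and a transcript, 10.3% and 10.0% lay within 2 kb, where an even spread over the listed range gives 10%.

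**Figure D1:**
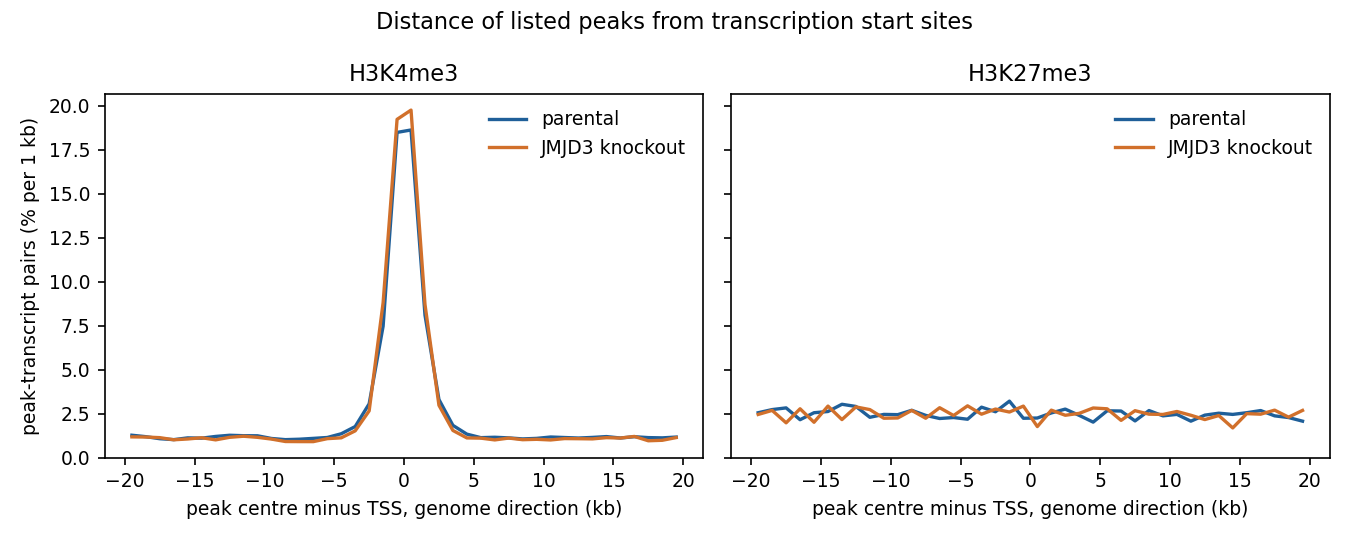
Percent of listed peak-transcript pairs per 1 kb of distance between peak centre and TSS, for H3K4me3 (left) and H3K27me3 (right), with 1 line per genotype. H3K4me3 pairs concentrate at the TSS in both genotypes, with 52.7% and 56.5% of pairs within 2 kb, and H3K27me3 pairs are spread evenly.

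The targeted gene carried promoter H3K4me3 in both genotypes and no H3K27me3 peak within 20 kb in either. KDM6B (NM_001080424, TSS at 7743234 on chromosome 17, hg19) had 10 promoter H3K4me3 peaks with a summed width of 3041 bp in parental cells and 4 peaks of 710 bp in knockout cells, a log2 ratio of -2.10. Within 20 kb of the TSS, 17 parental peaks stood against 6 knockout peaks. The parental peak nearest to the TSS, from 7742683 to 7743110, had no counterpart in the knockout list, whose nearest peak ran from 7745732 to 7745903. Of the 11190 genes marked in both lists, 1119 (10.0%) had a lower ratio than KDM6B. Its neighbourhood narrowed too: the 102 genes marked in both lists between 0 and 10 Mb of chromosome 17 had a median log2 ratio of -1.93, and 40 of them lay below KDM6B. A histone mark at the promoter does not show whether the coding sequence was disrupted, so these values do not check the knockout.

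**Figure D2:**
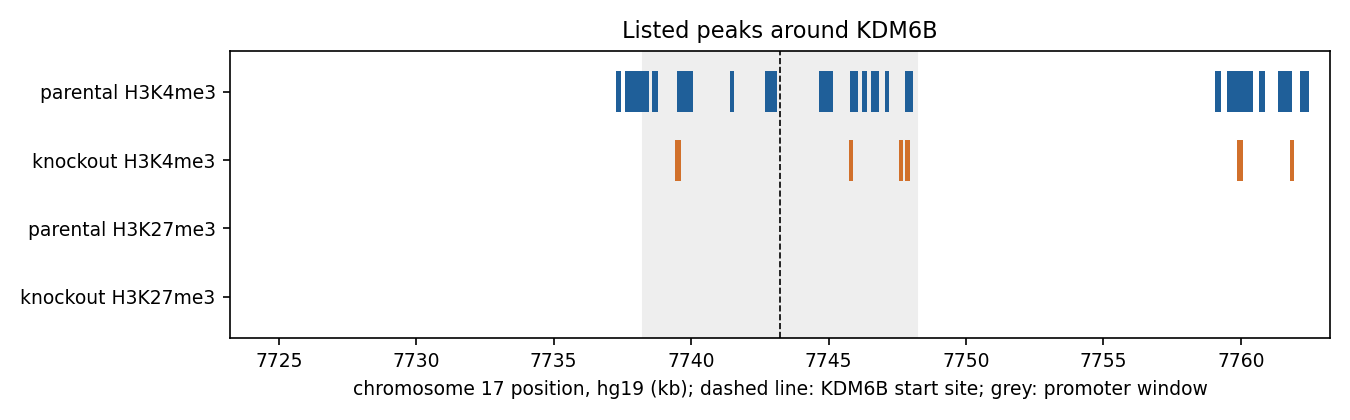
Listed peaks around KDM6B on chromosome 17 (hg19, kb), with 1 row per library, the TSS at 7743234 as a dashed line and the promoter window of 5 kb on either side in grey. The parental H3K4me3 row holds 17 peaks and the knockout row 6, and both H3K27me3 rows are empty.

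H3K4me3 regions were fewer and narrower in the knockout list. The knockout list held 0.745 times as many peaks as the parental list (95% interval 0.733 to 0.758), and the median peak was 260 bp wide against 359 bp. Among the 11190 genes with promoter H3K4me3 in both lists, the median log2 ratio of summed promoter width was -1.01 (quartiles -1.49 and -0.61), and 453 genes (4.05%) were wider in the knockout list. Promoter H3K4me3 was listed in parental cells only for 1709 genes, 13.2% of those marked there, and in knockout cells only for 178 genes. The genes marked in parental cells only had narrow regions there, with a median of 499 bp against 1708.5 bp for genes marked in both.

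Knockout H3K4me3 peaks lay mostly inside parental regions. Of the knockout peaks 88.7% (88.3 to 89.1) overlapped a parental peak, and of the parental peaks 52.6% (52.1 to 53.1) overlapped a knockout peak. Parental peaks that were overlapped had a median width of 613 bp, against 235 bp for the others. When 50% of the parental peak had to be covered, its share was 22.7%, and with reciprocal overlap the knockout share was 26.2%. Lists of equal length gave 346 genes marked in knockout cells only, and peaks of at least 300 bp, a limit chosen after seeing the data, gave 3564 genes marked in parental cells only.

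The widest promoter H3K4me3 regions present in parental cells only were those of GMNN, BCOR and EMP3. GMNN, the replication licensing inhibitor geminin, had 7 peaks of 3273 bp in parental cells, the widest from 24775754 to 24777090 on chromosome 6. BCOR, a corepressor found in a variant Polycomb complex, had 2730 bp and HCFC1, a transcriptional coregulator, had 2403 bp; both lie on the X chromosome, whose share of the H3K4me3 list fell the most of all chromosomes. EMP3, ZUFSP, ZBTB5 and RFX7 had 2723, 2338, 2284 and 2264 bp, and IFITM1, an antiviral membrane protein, had 2205 bp. The widest regions present in knockout cells only were smaller. ZNF329 led with 1020 bp, followed by CD38, a surface ectoenzyme, with 851 bp, P3H3 with 721 bp and SERPINB2, a serine protease inhibitor, with 646 bp. SYNE4, LAX1, VIT and KCND3 had 622, 618, 592 and 541 bp. With a promoter window of 10 kb EMP3, P3H3, SERPINB2 and SYNE4 were marked in both lists and differed by -3241, 268, -41 and -41 bp. When peaks counted for their nearest gene only, SYNE4 was unmarked in both lists and HCFC1 had 435 bp. Within 1 kb of the TSS all 8 genes of the first group and 6 of the 8 of the second kept their state, and when only peaks that span the TSS counted, 2 (BCOR and EMP3) and 0 did.

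Among genes marked in both lists, the transcription factors FOXP1, BCL11A and NR2F2 and the corepressor IRF2BP2 lost the most width. FOXP1 had 9862 bp in parental and 3019 bp in knockout cells, BCL11A 8090 and 1676 bp, NR2F2 7377 and 2266 bp, and IRF2BP2 7279 and 1839 bp. The widest gains were at ZNF350, from 221 to 1827 bp, DDAH2, from 182 to 1288 bp, IGLL1, from 677 to 1637 bp, and the potassium channel gene KCNH2, from 1028 to 1878 bp. BCL11A and IGLL1 had the opposite sign within 1 kb of the TSS (314 and -305 bp), and DDAH2 within 10 kb (-2209 bp). DDAH2 was unmarked in both lists within 1 kb and when peaks counted for their nearest gene only. When only peaks that span the TSS counted, FOXP1, NR2F2 and ZNF350 kept their sign and the other 5 genes were unmarked.

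Regulators of granulocyte development kept promoter H3K4me3 in both genotypes. Of 25 listed myeloid transcription factors, 22 were marked in both lists, EGR1 in parental cells only (886 bp) and TAL1, a factor of early blood cells, in knockout cells only (382 bp); the list's net change of 0 lay at percentile 87.2. MYC, which is amplified in HL-60, stayed broad, with 7422 bp in parental and 6598 bp in knockout cells, a log2 ratio of -0.17. SPI1 (-0.61), CEBPD (-0.79) and CEBPA (-0.91) also narrowed by less than the median gene, while CEBPE (-1.33) and CEBPB (-2.23) narrowed by more. The CEBPB difference had the opposite sign when peaks counted for their nearest gene only (205 bp), as did CEBPD within 1 kb of the TSS (250 bp). None of these genes had promoter H3K27me3 in either genotype.

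Genes of mature myeloid cells differed in both directions. Among 18 listed granule proteins, 4 were marked in parental cells only, of which RNASE2 had 449 bp and BPI 364 bp, and 2 in knockout cells only, S100A8 with 431 bp and the gelatinase MMP9 with 377 bp; the net change of -11.1% lay at percentile 85.4. MMP9 was marked in both lists within 10 kb, with a difference of -69 bp. Among 21 listed surface receptors, FPR1 (332 bp) and ITGAM (146 bp) were marked in parental cells only, and CSF1R (188 bp) and FCGR1A (154 bp) in knockout cells only. The net change of 0 lay at percentile 95.2, and at 98.5 with lists of equal length. The 11 receptors marked in both lists had a median log2 ratio of -1.52, at percentile 1.75, which was 1 of 17 medians outside the limits. All 11 of the 18 listed inflammatory and NF-kB response genes that were marked at all were marked in both lists, at percentile 86.6.

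Interferon-stimulated genes and developmental regulators with promoter H3K4me3 in 1 genotype had it in the parental list. Of 23 listed interferon-stimulated genes, 18 were marked in parental and 10 in knockout cells; the 8 marked in parental cells only included IFITM1, IFITM2 (1019 bp), IFI6 (772 bp) and OAS3 (697 bp). The net change of -34.8% lay at percentile 19.6 among lists matched on width and at 0.03 among unmatched lists. The matched random lists averaged -26.4%. Their matching includes the knockout width and takes up a part of the loss, so 19.6 does not show the loss to be ordinary. Among lists matched on parental width alone the percentile also stayed inside the limits. HOX genes, which set body axis identity, were marked at 13 members in parental and 6 in knockout cells out of 33; HOXB5 (1196 bp), HOXC10 (614 bp), HOXA7 and HOXA9 were marked in parental cells only. HOXA7 and HOXA9 share 1 region of 2 peaks (564 bp), of which the wider, from 27200843 to 27201160 on chromosome 7, lies 4705 bp from the TSS of HOXA7 and -4148 bp from that of HOXA9. With a window of 1 kb none of these 4 genes was marked in either list. The net change of the HOX list, -21.2%, lay at percentile 11.0, and at 1.65 among unmatched lists.

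Among 58 listed developmental transcription factors outside HOX, 8 were marked in parental cells only and 0 in knockout cells only. DLX1 had 987 bp in parental cells, IRX3 914 bp, TWIST1 876 bp and LHX2 752 bp. The net change of -13.8% lay at percentile 2.42, the only value outside the limits among 34 pairs of list and mark. By chance 1.7 would arise if every pair could reach the limits. Matching on width fixed H3K27me3 lists with no marked member at percentile 50, so these pairs could not. The value of the developmental transcription factors returned inside the limits under 6 of 11 alternatives, at percentile 42.5 for the widest peaks of each list and 10.3 for unmatched lists. Among 40 listed signalling ligands and receptors of development, DHH (542 bp), WNT7B (270 bp), WNT1 (155 bp) and WNT3 (146 bp) were marked in parental cells only, at percentile 9.39.

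Housekeeping and cell cycle promoters were marked in both genotypes with few exceptions. All 40 ribosomal protein and housekeeping genes were marked in both lists, with a median log2 width ratio of -0.93 and a net percentile of 54.7. Of 34 genes of the cell cycle and replication, 33 were marked in both lists, and CCNB1, cyclin B, in parental cells only with 1022 bp (percentile 58.9; 98.6 within 1 kb). CCNB1 and EGR1 lie between 50 and 140 Mb of chromosome 5, where the knockout list held 39.7% as many H3K4me3 peaks as the parental list. Of 28 cell cycle inhibitors and apoptosis genes, the caspase inhibitor gene XIAP on the X chromosome (868 bp), GADD45G (630 bp) and the death receptor gene TNFRSF10B (501 bp) were marked in parental cells only, at percentile 16.5. Of 35 genes of the H3K27 and H3K4 methylation machinery, 34 were marked in both lists and CBX2, a Polycomb subunit, in parental cells only with 1771 bp from 2 peaks. That list lay at percentile 56.4, and at 0.145 when only peaks that span the TSS counted. KDM6A, the related H3K27 demethylase on the X chromosome, had 3593 bp in parental and 726 bp in knockout cells (-2.31).

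Some markers of other lineages had promoter H3K4me3. Of 14 lymphoid markers 7 were marked in parental and 5 in knockout cells. ZAP70 (159 bp) and LCK (146 bp) were marked in parental cells only, at percentile 53.2; within 10 kb ZAP70 was marked in both lists and differed by 21 bp. Of 13 erythroid and megakaryocyte markers, 4 were marked in both lists and ITGA2B, the platelet integrin chain, was marked in knockout cells only (155 bp), at percentile 96.6 and at 98.0 among unmatched lists. Of 20 epithelial, fibroblast and neuronal markers, 3 were marked in both lists, and MAP2 (369 bp) and TUBB3 (170 bp) were marked in parental cells only, at percentile 22.2. Of 24 oncogenes and stem cell genes of acute myeloid leukaemia (AML), HOXA9 and FLT3 (146 bp) were marked in parental cells only and CD38 in knockout cells only. That list lay at percentile 81.5, at 98.0 within 1 kb and at 98.3 for peaks of at least 300 bp. Of 8 listed genes at loci known as deleted or amplified in HL-60, 7 were marked in both lists, at percentile 76.2. Of 38 list members named for a differing H3K4me3 state, 23 kept it within 1 kb of the TSS, and 4 (IFI6, OAS3, TAL1 and TWIST1) when only peaks that span the TSS counted; the others were unmarked in both lists. With a window of 10 kb DLX1, FLT3, MMP9, WNT1 and ZAP70 were marked in both lists, and when peaks counted for their nearest gene only HOXB5 and LCK were unmarked.

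**Figure D3:**
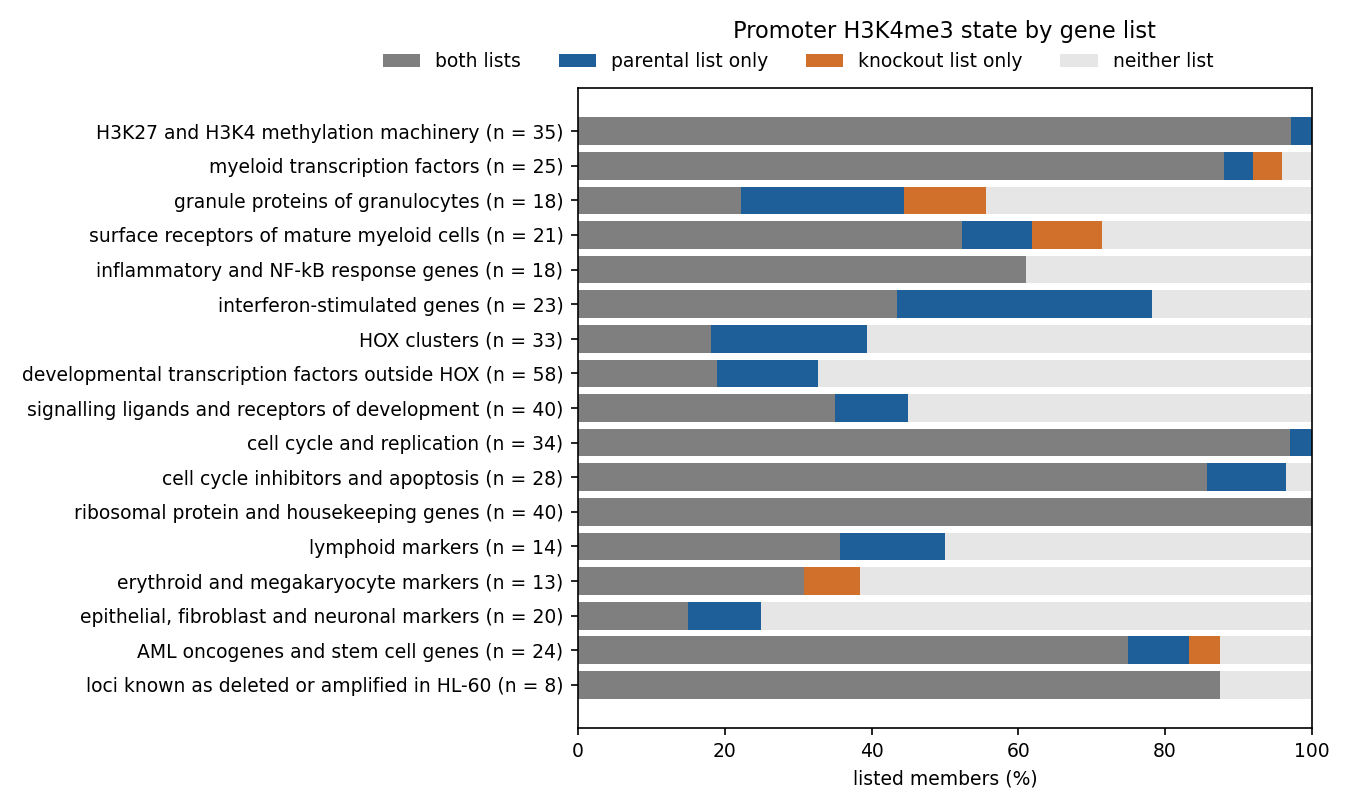
Percent of each gene list's members (n in brackets, members present in any file) with promoter H3K4me3 in both lists, the parental list only, the knockout list only or neither. Interferon-stimulated genes, HOX genes and developmental transcription factors have 8, 7 and 8 members in the parental list only and 0 in the knockout list only, and all 40 ribosomal protein and housekeeping genes are marked in both.

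H3K27me3 peaks were slightly fewer in the knockout list, and most did not overlap a parental peak. The knockout list held 0.904 times as many peaks as the parental list (95% interval 0.862 to 0.948), with 0.988 times the covered length and a median width of 1032 bp against 909 bp. Of the parental peaks 27.2% (25.8 to 28.7) overlapped a knockout peak, and of the knockout peaks 29.6% (28.0 to 31.2) overlapped a parental peak. Promoter H3K27me3 was listed for 429 genes in both genotypes, where independent lists give 45.9, for 495 genes in parental cells only and for 470 in knockout cells only. Among the 429 genes the median log2 width ratio was 0.01, and 218 were wider in the knockout list. When 50% of a peak had to be covered the overlap shares were 15.6% and 16.5%, and when only peaks that span the TSS counted the gene counts were 100 and 89.

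The largest losses of promoter H3K27me3 width among genes marked in both lists lay over genes of the epidermal cornified envelope on chromosome 1. SPRR2A lay under 1 parental peak of 13028 bp, from 153022348 to 153035375, and under 2 knockout peaks of 3265 bp. LCE1C went from 11423 to 716 bp, SPRR1A from 9536 to 1119 bp and LCE2C from 7457 to 1149 bp. The widest gains among genes marked in both lists were at FRMD6 (1867 to 7777 bp), CDON (374 to 4862 bp), C1orf61 (1424 to 5748 bp) and the collagen gene COL4A1 (1340 to 5190 bp). In parental cells only, the widest were C1orf87 (4110 bp), the calcium-binding protein gene CALB1 (3919 bp), LCE2B (3854 bp) and CAV1, caveolin (3774 bp), then DEC1, EGFLAM, KIRREL and TCF21 (3682, 3556, 3517 and 3339 bp). In knockout cells only, they were ARHGAP32 (6998 bp), PLAG1 (6646 bp), CREB5 (6027 bp) and MTUS2 (5187 bp), then FOXP2, CCDC181, IGF2BP2 and SOX6 (5047, 4513, 4460 and 4454 bp). The ARHGAP32 peak ran from 128887792 to 128894789 on chromosome 11. Many of these calls rest on the promoter window of 5 kb. With a window of 1 kb, LCE2C, FRMD6, CDON, COL4A1, C1orf87, CALB1, LCE2B, DEC1, EGFLAM, TCF21, PLAG1, CREB5 and FOXP2 were unmarked in both lists, and when only peaks that span the TSS counted KIRREL was too. With a window of 10 kb, CAV1, KIRREL, LCE2B and SOX6 were marked in both lists, with differences of -2187, -2568, -1468 and 6980 bp. The difference at LCE2C shrank there from -6308 to -1526 bp and that at C1orf61 from 4324 to 2056 bp. When peaks counted for their nearest gene only, DEC1 was unmarked in both lists. The differences at C1orf61, FRMD6, EGFLAM and TCF21 were then 2425, 3859, -1583 and -1175 bp. The 4 largest losses and 4 widest gains kept their sign with the window of 10 kb and for the nearest gene.

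Developmental transcription factors outside HOX gained and lost promoter H3K27me3 in equal number. Of the 58 members, 4 were marked in parental cells only, with SOX2, a pluripotency and neural factor, at 1999 bp, and 4 in knockout cells only, with DLX6 at 1997 bp, PAX2 at 1716 bp and PAX8 at 1371 bp (percentile 53.3). Among HOX genes HOXB9 alone was marked, in knockout cells, with 1508 bp (percentile 77.4). Among signalling genes FGF10 (463 bp), BMP6 (307 bp) and BMP4 (296 bp) were among 4 marked in parental cells only and SFRP2 (444 bp) was marked in knockout cells only (percentile 19.2); within 10 kb the SFRP2 difference was -688 bp. Among lineage markers outside blood, COL3A1 (1124 bp), SLC17A7 (1113 bp) and GAD1 (446 bp) were marked in parental cells only (percentile 18.4 for the list). CD163 (382 bp), OAS2 (510 bp) and HBE1 (715 bp) were the only members of the surface receptor, interferon and erythroid lists with promoter H3K27me3, each in parental cells only (percentiles 30.1, 30.1 and 27.4). DMRTA1 (1063 bp) was the only marked gene of the loci known as deleted or amplified in HL-60, in knockout cells only (percentile 77.5). Of the genes named in this paragraph, PAX2 and HBE1 alone kept their state with a window of 1 kb, and PAX2 alone when only peaks that span the TSS counted; the others were unmarked in both lists. With a window of 10 kb DLX6 and SFRP2 were marked in both lists, and when peaks counted for their nearest gene only DLX6 and FGF10 were unmarked.

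The remaining lists had no member whose promoter H3K27me3 state differed. Myeloid transcription factors, inflammatory genes, cell cycle inhibitors and housekeeping genes had 0 marked members in either genotype. The methylation machinery had 1 (CBX7), the granule proteins 1 (S100A12), the cell cycle list 1 (CDK6), the lymphoid markers 2 (EBF1 and RAG1) and the AML list 2 (MECOM and RUNX1T1), each marked in both lists and chosen here after their values were seen. Their percentiles ran from 43.7 to 50, where a list with 0 marked members lies at 50 by construction.

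Both marks at 1 promoter were less frequent than independent lists would give. In parental cells 208 genes carried both marks where 659 were expected, and in knockout cells 152 where 565 were expected; 95 genes did so in both genotypes. Of the 1709 genes with promoter H3K4me3 in parental cells only, 17 had promoter H3K27me3 in knockout cells only, where 44.4 were expected. CREB5 was 1 of them, with 667 bp of H3K4me3 in parental cells. Peaks of the different marks rarely coincided: 2.46% of parental and 1.36% of knockout H3K27me3 peaks overlapped an H3K4me3 peak of the same genotype. The marks come from separate libraries, so both on the same chromatin fibre was not measured. When only peaks that span the TSS counted, the numbers were 23 and 10.

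Peak counts did not differ evenly along the genome. The X chromosome held 806 parental and 298 knockout H3K4me3 peaks, a log2 change in its share of the list of -1.01 (95% interval -1.20 to -0.82). Its share of the H3K27me3 list changed by -0.74 (-1.19 to -0.29), from 113 to 61 peaks. Chromosome 5 lost H3K4me3 share (-0.32), while chromosomes 18 (0.35) and 13 (0.25) gained. For H3K27me3, chromosome 12 gained share (0.58, 0.28 to 0.87) and chromosome 19 lost it (-1.07, -1.74 to -0.39). Of 23 chromosomes the interval excluded 0 for 5 in H3K4me3 and for 8 in H3K27me3; clustered peaks make these intervals too narrow.

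**Figure D4:**
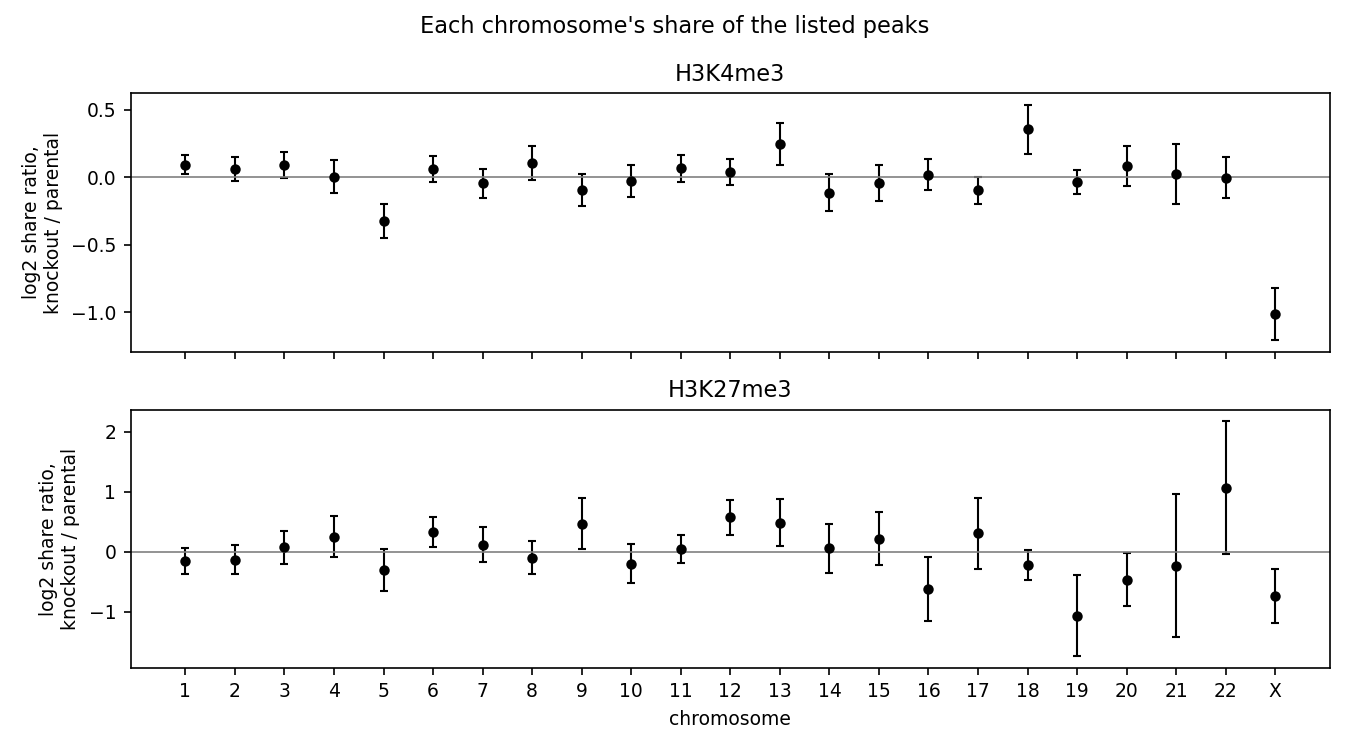
Log2 ratio of each chromosome's share of the knockout list to its share of the parental list, for H3K4me3 (top) and H3K27me3 (bottom); bars are 95% intervals for counting error only. The X chromosome lies at -1.01 and -0.74, and chromosome 18 at 0.35 for H3K4me3.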

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

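The tests on housekeeping promoters, on H3K27me3 at genes that lost H3K4me3, on H3K27me3 peaks of the X chromosome and on H3K4me3 in the chromosome 12 segment were chosen after the results were seen; the width-matched test and the exchange of peak clusters were fixed before theirs.

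Each library has peak numbers with no line in its list. The numbers run beyond the peaks that have a line by 5054 in parental H3K4me3, 2750 in knockout H3K4me3, 13805 in parental H3K27me3 and 12384 in knockout H3K27me3. In the H3K27me3 lists 20.6% and 20.7% of the numbers have a line; the positions of the rest are unknown, and no peak behind them was analysed here.

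H3K4me3 peaks were fewer and narrower in the knockout list. Listed gains of H3K27me3 covered little of this loss: 0.995% of the genes that lost promoter H3K4me3 gained promoter H3K27me3, where independent lists give 2.60%. Only 470 genes gained listed promoter H3K27me3, against 1709 that lost promoter H3K4me3, so listed gains could not have covered most of the loss. Gains of H3K27me3 that the lists do not hold cannot be judged. A lower sensitivity of the knockout H3K4me3 list may account for the loss of H3K4me3, since ribosomal protein and housekeeping promoters narrowed with the rest. Their median log2 ratio was -0.93, against -1.01 for all genes. A genome-wide fall of H3K4me3 in cells without JMJD3 would give the same values and stays open, untested. With 1 library per genotype and neither depth nor inputs at hand, these explanations were not separated.

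The X chromosome lost more promoter H3K4me3 than other chromosomes. The narrower promoters of X genes did not fully account for it: 46.3% of X genes marked in parental cells were not marked in knockout cells, against 28.6% (24.7 to 32.4) of autosomal genes matched on parental width. Without matching, the autosomal share was 12.3%, so narrower promoters may account for a part of the excess on X. H3K27me3 peaks on X were also relatively fewer, at 0.597 times the ratio of the whole list (0.437 to 0.815). A lower copy number of X sequence in knockout than in parental cells could give this, but these peaks cannot decide it. H3K27me3 share also changed where H3K4me3 share hardly did. The log2 changes were -1.07 for H3K27me3 and -0.03 for H3K4me3 on chromosome 19, and 0.58 and 0.04 on chromosome 12. H3K4me3 peaks on X were narrow in both genotypes, with medians of 263 bp against 359 bp in the whole parental list and 208 bp against 260 bp in the knockout list. These values do not separate a copy difference between genotypes from narrower calls on X in both. An effect of JMJD3 on X genes was not tested and stays open.

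H3K27me3 peaks between 10 and 30 Mb of chromosome 12 went from 4 in parental to 57 in knockout cells, over genes that include SOX5 and GRIN2B. H3K4me3 peaks there showed no relative rise, with a ratio of knockout to parental peaks 0.982 times that of the whole list (0.799 to 1.21). How peak counts follow copy number was not measured, and the interval covers counting error only. A copy gain therefore stays open too. Chance turnover of clustered peaks stays open: when 1084 clusters were exchanged between the genotypes at random, 5.05% of 10000 draws gave some 20 Mb window with an excess of at least 53 peaks, a share at the 5% limit. A gain of H3K27me3 in cells without its demethylase is a hypothesis that stays open, untested.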

How the results depend on the processing

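Peaks of at least 300 bp, gene counts without the regions where H3K4me3 peak counts fell most and random lists matched on parental width were alternatives chosen after seeing the data; the rest were fixed before. Peak ratios stayed below 1 for both marks, and for H3K4me3 the ratio was 0.815 with merging and 0.517 for peaks of at least 300 bp. Cutting lists by number fixes the ratio, so it was not computed for the widest peaks or lists of equal length.

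The parental H3K4me3 share overlapped was 55.8% for the widest peaks, 63.6% for lists of equal length, 22.7% with 50% of the peak covered, 19.5% with reciprocal overlap, 72.8% with merging, 53.3% on chromosomes 1 to 22 and 44.5% for peaks of at least 300 bp. The knockout share was 86.2%, 84.1%, 79.2%, 26.2% and 90.8% under the first 5 of these and 92.0% under the last. For H3K27me3 the parental share was 28.8% for lists of equal length, and the shares were 15.6% and 16.5% with 50% covered and 8.44% and 9.34% with reciprocal overlap. Stricter overlap lowers a share by construction; other causes were not tested.

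Genes with H3K4me3 in parental cells only outnumbered those in knockout cells only in each alternative. The first count was 3564 for peaks of at least 300 bp and 1378 without the X chromosome and the regions of chromosomes 5, 9 and 17, and the second 291 for the widest peaks, 346 for lists of equal length, 274 within 1 kb, 275 for the nearest gene and 108 for peaks of at least 300 bp. H3K27me3 counts in parental and knockout cells only were 305 and 312 for the widest peaks, 190 and 136 within 1 kb, and 100 and 89 for peaks that span the TSS. Genes with both marks numbered 97 and 80, 67 and 38, and 23 and 10 under these settings, and 267 in knockout cells within 10 kb. A smaller window leaves fewer genes by construction.

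For H3K27me3, no list's percentile changed its side of the limits. H3K27me3 lists with few or no marked members had little room to do so. Over both marks, 360 of 374 percentiles recomputed for the gene lists kept their side of the limits. Developmental transcription factors moved inside them at 42.5 for the widest peaks, 3.49 for lists of equal length, 13.4 within 1 kb, 62.8 for peaks that span the TSS, 16.1 for peaks of at least 300 bp and 10.3 for unmatched lists. Lists that moved outside were interferon-stimulated genes (0.03), HOX genes (1.65) and erythroid markers (98.0) among unmatched lists, the AML list (98.0) and the cell cycle list (98.6) within 1 kb, the AML list for peaks of at least 300 bp (98.3), surface receptors for lists of equal length (98.5) and the methylation machinery for peaks that span the TSS (0.145). The cause was not tested.

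Of 1068 recomputed width differences of named genes 13 changed sign and 320 moved by more than 1.5 times. In H3K4me3, knockout minus parental width became 314 bp at BCL11A, 250 bp at CEBPD and -305 bp at IGLL1 within 1 kb; -2209 bp at DDAH2, -69 bp at MMP9, -41 bp at SERPINB2 and SYNE4 and 21 bp at ZAP70 within 10 kb; 205 bp at CEBPB and 227 bp at FRMD6 for the nearest gene; and 222 bp at CDON for the widest peaks and for peaks of at least 300 bp. In H3K27me3, SFRP2 became -688 bp within 10 kb. The cause was not tested. Unknown depth limits each comparison of list length and width.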

Other observations

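Gene families were grouped by symbol after the values were seen, and no test was made of their H3K27me3. Olfactory receptor genes had promoter H3K27me3 at 27.1% of 177 listed symbols in parental and 27.7% in knockout cells. Of these genes 26 were marked in parental cells only and 27 in knockout cells only. Over all symbols, promoter H3K27me3 was listed at 5.11% in parental and 4.97% in knockout cells. Late cornified envelope and small proline-rich genes had it at 85.7% of 28 symbols in parental and 60.7% in knockout cells, with 7 in parental cells only and 0 in knockout cells only; they share 43 parental and 22 knockout peaks, so neighbours are not independent. Keratin-associated protein genes went the other way, from 10.6% to 31.9% of 47 symbols, resting on 4 and 10 peaks. Of 18 matrix metalloproteinase genes, 0 were marked in parental and 6 in knockout cells (MMP3, MMP12, MMP13, MMP24, MMP26 and MMP27, on 7 peaks). Beta-defensin genes had it at 33.3% of 18 symbols in each genotype, protocadherin genes at 5% of 20 symbols in parental and 0% in knockout cells, and zinc finger genes at 3 of 374 symbols in both genotypes, 2 in parental cells only and 3 in knockout cells only. Histone genes had no promoter H3K27me3 at any of 68 symbols, and 51 had promoter H3K4me3 in both genotypes.

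Several autosomal regions held fewer H3K4me3 peaks in the knockout list, as the X chromosome did; they were singled out after the values were seen. The knockout list held 252 peaks against 635 between 50 and 140 Mb of chromosome 5, 21 against 83 between 10 and 30 Mb of chromosome 9 and 112 against 328 between 0 and 10 Mb of chromosome 17, the region of KDM6B. Among windows of 10 Mb with at least 20 parental peaks, all 12 on X lay under the genome's 74.5%. Their knockout counts ran from 25.4% to 63.6% of the parental counts. On autosomes 16 of 275 windows had a knockout count under 50% of the parental count. That limit is stricter than 74.5%, under which autosomal windows were not counted, so the counts for X and autosomes are not comparable. Windows from 60 to 80 Mb of chromosome 14 and from 0 to 10 Mb of chromosome 10 were also among these 16. For chromosome 18 the knockout count was 95.3% of the parental count. Parental H3K4me3 peaks had median widths of 273, 225 and 279.5 bp in the named regions of chromosomes 5, 9 and 17. The parental median was 397.5 bp on chromosome 18 and 359 bp in the whole list. Regions were compared by ratios of counts, and overlap was not computed by region.

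H3K27me3 differences of other regions went both ways, and the windows named here were chosen after the values were seen. Higher knockout counts lay between 25 and 30 Mb of chromosome 6, with 2 parental and 24 knockout peaks over a cluster of olfactory receptor genes, and between 20 and 40 Mb of chromosome 13, with 13 and 43 peaks that include the promoters of FLT1 and POSTN. Lower knockout counts were as large: the 20 Mb windows that start at 140 Mb of chromosome 1 and at 30 Mb of chromosome 18 had differences of -40 and -35 peaks, and those that start at 20 Mb of chromosomes 6 and 13 had 30 each. When peak clusters were exchanged at random between the genotypes, the median of the largest excess was 40 peaks, so differences of 30 lie below what random exchange usually gave.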
